A study of Mus musculus with 3 samples.

How the data were processed

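SRF ChIP-seq libraries of whole cornea from 1 Dstn-corn1 mutant and 1 wildtype group of mice and 1 input library were sequenced on an Illumina HiSeq instrument, per the labels. Genotype was taken from the sample titles. The growth protocol in the labels names mutant mice for all 3 libraries, which conflicts with the title of the wildtype library, and the genotype of the input is not given in the sources used here. Reads were aligned with BWA to mm10, per the submitters' processing notes. The interval caller, its threshold, duplicate removal and any scaling between libraries are not given in the sources used here.

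The authors deposited intervals called per library, merged regions with values from both libraries, and genes with their assigned intervals. Signal values are, per the file headers, the peak value and the average value of each interval or region; peak values are whole numbers and are called heights here. The ratio of wildtype to mutant peak values in the deposited table was not used, and the ratios were recomputed. No input values were used here. Coordinates are given as the files list them, and whether starts count from 0 is not given in the sources used here. Gene assignments and distances to gene starts are the authors'.

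Ratios are log2 of mutant over wildtype peak height after adding 1 to each, which understates differences of low regions. No fold is given where a library is listed at 0. Overlaps needed at least 1 bp and were counted with bedtools 2.31.1. Promoters were within 1 kb of a gene start. Shares carry exact binomial 95% intervals and medians carry order-statistic 95% intervals; both cover counting error over regions and not variation between animals. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures in matplotlib 3.10.9.

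For gene lists, 13 lists were fixed before the data were examined: actin cytoskeleton and MRTF-linked targets, actin filament turnover, immediate early and TCF-linked targets, SRF and its cofactors, corneal epithelium and keratins, stroma, corneal endothelium, vessels, smooth muscle and pericytes, leukocytes, inflammation, proliferation, and unrelated tissues. A gene was bound where the authors assigned it an interval. Random lists were drawn 10000 times from 26215 reference genes with a curated transcript; 15868 of the 16697 genes with an interval matched them by identifier. For ratios each gene took its region of highest mean height, and random lists were matched on 20 height classes. Where promoter and CpG island location were matched too, only 5 height classes were used. Of regions tied on mean height the first listed was taken, a rule the fixed design left open. Some members share a region and some genes stand in more than 1 list. Percentiles describe these libraries and are not p-values.

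Named genes follow a rule fixed before the data were examined: Dstn and Srf; the 10 highest regions of each library; the 10 largest ratios each way among regions with an assigned gene, a called interval and a height of at least the median of the higher library (20 in mutant, 29 in wildtype); and up to 5 bound members of each list with the highest mean height. For several lists only some of these members are named.

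On simulated log2 ratios for 31850 regions, 4.00% of 200 unshifted lists of 24 regions fell outside the central 95%, and 92.5% of lists shifted by 0.5 lay above it. The simulated lists held independent regions of the upper height classes, with the same spread at every height. Smaller lists and lists with shared regions were not simulated, so these shares do not describe them. The alternatives tried were a stricter height threshold, other overlap rules, the average value, a pseudocount of 5, scaling to a common median, a 5 kb promoter distance, and other gene assignments and matchings. SRF motif searches were not run, as no genome sequence was used here.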

Results

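Chromatin immunoprecipitation with an antibody against SRF, the serum response factor, followed by sequencing was carried out on whole mouse cornea at about 8 weeks of age. SRF is a transcription factor of actin cytoskeleton genes and of immediate early genes, which respond within minutes to growth signals. A library came from Dstn-corn1 mutants, which lack functional destrin, an actin-depolymerizing protein, and another came from wildtype mice. An input library without antibody was the third; its values were not used here. Each genotype had 1 library, so no difference below has a replicate check and no p-value is given. The values are peak heights, the signal at the highest point of a region. Read totals were not used here, so the depth behind the heights is unknown.

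The mutated gene was looked at first, as a check of the labels. Dstn had 3 regions on chromosome 2 (mm10), and all 3 were listed at 0 in the mutant library. The region over the gene start (143914824 to 143915669, centre 85 bp upstream, listed at -85) had a wildtype height of 35. The region inside the gene (143929818 to 143930256) had a wildtype height of 11, and the region past its end (143945654 to 143946056) one of 13. Neighbouring regions had signal in both libraries, with 5 in mutant and 24 in wildtype at Gm11686 and 17 and 34 at Rrbp1. The 3 regions at 0 spanned 143914824 to 143946056. The flanking regions with mutant signal ended at 143877794 and started at 143980678, and the sequence between regions was not measured. The run at Dstn was the longest of the 36 runs of neighbouring regions at 0, and the other runs held 1 region each. The zeros at Dstn stood in the library titled mutant, so these values and the titles did not conflict. These values alone do not tell missing or unmappable DNA at Dstn from lost SRF binding.

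**Figure D1:**
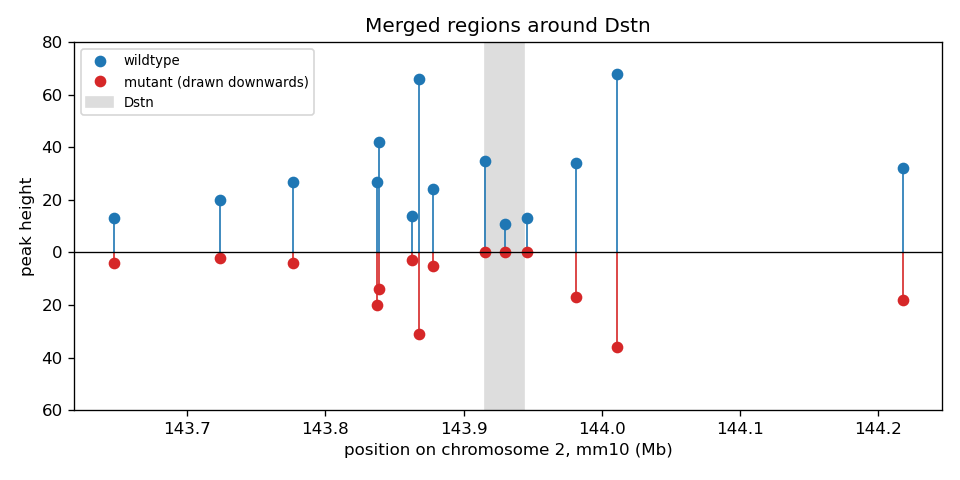
Peak heights of merged regions around Dstn on chromosome 2 (mm10, Mb), with wildtype drawn upwards and mutant downwards, 1 point per region and library. The 3 regions at Dstn, shaded, had heights of 35, 11 and 13 in wildtype and were listed at 0 in mutant.

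Srf itself carried signal in both libraries. Its highest region, inside the gene on chromosome 17 (46552629 to 46553797), reached 48 in mutant and 51 in wildtype, a log2 ratio of -0.086. The region over its start (46555631 to 46556638) reached 36 and 41, a log2 ratio of -0.18, and the third (46549017 to 46549743) 8 and 21, a log2 ratio of -1.29. With the libraries scaled to the same median over regions called in both, the first and second of these regions were higher in mutant, at log2 ratios of 0.97 and 0.87. The average height of the first was also higher in mutant, at 18.8 against 14.9.

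The first comparison asked where SRF was bound in the mutant and wildtype cornea. Many of the highest regions were the same in both libraries. Slc39a10, a zinc transporter gene, had the highest region of each, at 173 in mutant and 319 in wildtype. Ddx17, an RNA helicase gene, followed with 167 and 313. A region shared by Kcnk4, Gpr137 and Bad reached 166 and 292, and one at Hnrnpa2b1 and Cbx3 160 and 303. Sept7, a septin gene, reached 150 and 293, and Vps13d 128 and 303. These 6 regions were among the 10 highest of both libraries. The remaining regions among the mutant 10 were at Rn18s-rs5, a ribosomal RNA gene with many copies (151 and 222), Dagla (145 and 270), Gbas (132 and 258) and Zswim6 (131 and 199). Those among the wildtype 10 were at Epc2 (123 and 300), Snx18 (122 and 293), Slc25a25 (117 and 287) and Palb2 with Dctn5 (89 and 280).

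The authors called 16399 intervals in mutant and 31282 in wildtype. Of the mutant intervals, 95.9% overlapped a wildtype interval (exact binomial 95% interval 95.6 to 96.2), whereas 50.2% of the wildtype intervals overlapped a mutant interval (49.6 to 50.7). With equal numbers of the highest intervals from each library, these shares were 75.5% and 74.8%. Of 31850 merged regions, 15587 were called in both libraries, 15593 in wildtype only and 670 in mutant only. Promoters, taken as positions within 1 kb of a gene start, held 26.9% of mutant intervals (26.2 to 27.6) and 22.2% of wildtype intervals (21.8 to 22.7). The intervals on these shares cover counting error only.

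Peak heights were lower in mutant at 95.4% of merged regions. The median log2 ratio of mutant to wildtype was -1.10 (95% interval -1.11 to -1.10 over regions). By a rule of size, 18806 regions were at least 2-fold higher in wildtype and 132 at least 2-fold higher in mutant. How the authors scaled the libraries is not given in the sources used here, and the split depends on it. After scaling to the same median over regions called in both, the counts were 2962 and 1459 and the median was -0.090. Differences between gene groups are therefore given relative to other genes, whose median over 16697 genes was -1.08.

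**Figure D2:**
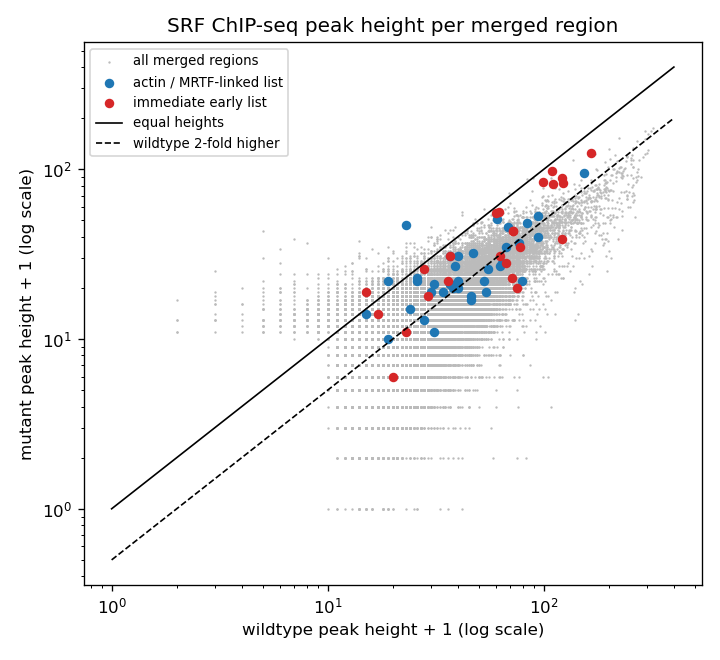
Mutant against wildtype peak height plus 1 for each merged region, both axes on a log scale, with regions of the actin and the immediate early list coloured. Most grey points lie below the line of equal heights, with a median log2 ratio of -1.10, and the immediate early regions lie closer to that line, with a median of -0.63.

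Under the naming rule, the largest ratio in favour of the mutant library was at the start of Glipr1, in a region also assigned to Krr1, with a height of 42 in mutant and 4 in wildtype. Bai1 had 29 and 4, Kcnab1 33 and 5, Arhgap25 38 and 6, and Nedd9, a focal adhesion scaffold gene, 21 and 4. Slc20a2 had 23 and 5, Wdr7 23 and 6, Tspan9 21 and 6, Arid5b 23 and 7, and a histone cluster with Hist1h1b 29 and 9. None of these 10 regions was called in wildtype. Apart from Glipr1, the nearest to its named gene was the histone cluster region, listed at -1892 bp from the start of Hist1h1b. The others lay from 15593 bp (Slc20a2) to 212740 bp (Kcnab1) from the start of the named gene. The largest ratios in favour of wildtype, Dstn aside, were at Efcab6 (1 in mutant and 82 in wildtype), Pik3r6 (1 and 74), Kif26a (1 and 57) and Gm15753 (2 and 56). Cdk14 (1 and 35), Clip4 (5 and 104), Soga2 (1 and 32), Ptprm (3 and 59) and Plod3 (4 and 74) completed the 10, and none of them was called in mutant. Dstn aside, these regions lay from 6047 bp (Gm15753) to 587866 bp (Ptprm) from the start of the named gene.

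The next comparison asked which groups of genes were bound. The immediate early list, which also holds TCF-linked SRF targets, was bound in 22 of 25 members in mutant and 24 in wildtype. Random lists of the same size had a median of 11 and 15. Mir143 and Mir145 in this list share a region and count as separate members. Egr1, a zinc finger transcription factor gene, had heights of 123 and 164, and Fos, a subunit of the AP-1 factor, 97 and 108 at a region centred 12140 bp past its start. Heights given for list members are those of the highest region the authors assigned, which can lie far from the gene start or be shared with other genes. Genes of the actin cytoskeleton linked to the SRF cofactor MRTF were bound in 35 of 40 members in mutant and 37 in wildtype, against 18 and 24 in random lists. Actin filament turnover genes were bound in 22 and 23 of 27 members, against 12 and 16. Dstn, the mutated gene, counts as a member here and in the list median below, with 0 in mutant and 35 in wildtype. All 3 lists lay above the 97.5th percentile of 10000 random lists in both libraries. These random lists came from all reference genes and were not matched on promoter type, CpG islands or gene activity. A high percentile is therefore not particular to SRF-linked genes. Smooth muscle genes were bound in 8 of 10 members in mutant and 9 in wildtype, at percentiles of 98.3 and 97.4, and of 96.0 and 93.5 among lists matched on gene length. Within 1 kb of a start, 0 of them were bound in mutant and 1 in wildtype. Proliferation genes were bound in 9 of 13 members in mutant and 13 in wildtype, at percentiles of 95.6 and 99.965. Differences between the libraries in these percentiles were not tested. Counting only intervals within 1 kb of a gene start, the actin list was inside the central range, with percentiles of 95.7 and 94.1.

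The remaining lists were bound within the central 95% of random lists in both libraries. Corneal epithelium and keratin genes were bound in 16 of 33 members in mutant and 21 in wildtype, stroma genes in 7 and 11 of 16, and corneal endothelium genes in 4 and 5 of 8. Vessel genes were bound in 5 and 9 of 13 members, inflammation genes in 8 and 10 of 18, and SRF and its cofactors in 5 and 6 of 7. With only intervals at or above the median height of 24, SRF and its cofactors were at percentile 97.675 in wildtype, above the central range, and at 67.3 in mutant. Leukocyte genes were bound in 6 and 7 of 18, at percentiles of 17.1 and 3.97; within 1 kb of a start these were 1.125 and 0.11. Genes of unrelated tissues, the background list, were bound in 8 and 14 of 25, at percentiles of 9.82 and 34.3. Within 1 kb of a start, 0 genes of the leukocyte, vessel and background lists were bound in either library. The background list was then at percentiles of 0.29 and 0.01 and the vessel list at 3.23 and 0.685, so that all but the mutant vessel value lay below the central range.

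The last comparison asked which gene groups kept more or less of their wildtype height in the mutant. The immediate early list had a median log2 ratio of -0.63 over 24 bound genes (95% interval -1.06 to -0.26), above all 10000 random lists matched on height, whose median was -1.17. Besides Egr1 and Fos, Dusp5, a phosphatase gene, had heights of 88 in mutant and 121 in wildtype, Ier2 82 and 122, and Egr3 81 and 109. Of the 24 genes, 18 were above the median of all genes, and 8 were at least 2-fold lower in mutant. Among these 8 were Nr4a1 (38 and 121) and Dusp1 (19 and 74), outside the naming rule and added after their values were seen. The actin and MRTF list had a median of -0.83 over 37 genes (-1 to -0.66), at the 99.7th percentile, with 26 genes above the median of all genes. Actb, the beta-actin gene, had 94 and 153, Tpm1 52 and 93, Fhl2 39 and 93, Myh9, a nonmuscle myosin gene, 47 and 83, and Tagln2 36 and 76. With the average height in place of the peak height, the actin list was at the 92.8th percentile, inside the central range.

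The other 11 lists lay between the 2.5th and 97.5th percentiles of lists matched on height. Actin filament turnover had a median of -1.02 (percentile 78.2), with Cfl1, the cofilin gene, at 88 and 107, Diap1 at 47 and 151, Coro1c at 60 and 110, Ssh3 at 39 and 92 and Gsn at 44 and 80. Leukocyte genes had a median of -0.75 over 7 genes (percentile 97.4). With lists also matched on promoter and CpG island location they were at percentile 98.4, above the central range. In this list Cd68, at 88 in both libraries, shares its region with Mpdu1 and Eif4a1. Epithelium and keratin genes had a median of -0.87 (percentile 83.3), with Krt10 at 45 and 55, Clu at 28 and 77, Elf3 at 32 and 60, Krt8 at 37 and 49 and Tkt at 33 and 46. Smooth muscle genes had a median of -1.01 (percentile 74.4), with Smtn at 47 and 96, and inflammation genes -1.01 (percentile 71.0), with Tnfaip3 at 67 and 122 and Tnf at 16 and 68. Corneal endothelium genes had a median of -1.11 (percentile 58.0), with 111 and 240 at a region 35034 bp past the start of Col8a2 that is shared with Adprhl2, Tekt2 and Gm12945.

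The lowest medians were those of vessel genes, at -1.37 (percentile 11.5), with Eng, an endothelial TGF-beta coreceptor gene, at 96 and 217 in a region 42942 bp past its start shared with Fpgs, and Cdh5 at 11 and 49, and of SRF and its cofactors, at -1.32 (percentile 14.8), over 7 genes (95% interval -2.32 to 0.22). In that list Srf had 48 and 51, beside Mkl1 at 25 and 64, Elk3 at 22 and 48, Mkl2 at 11 and 36 and Myocd at 9 and 49. Its other 2 members, outside the naming rule and added after their values were seen, were Elk4 at 13 and 11 and Elk1 at 9 and 33. With regions within 1 kb of a start, the median of its 3 genes with one was 0.18, at the 98.8th percentile and above the central range. Stroma genes had a median of -1.28 (percentile 17.2), with Col1a1 at 53 and 130 and Fbln1 at 34 and 103. Proliferation genes had a median of -1.19 (percentile 27.4), with Aurka, a mitotic kinase gene, at 69 and 243 and Ccnd1 at 35 and 81. The background list had -1.23 (percentile 14.3), with Gfap at 33 and 78 and Myh6 at 28 and 76.

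**Figure D3:**
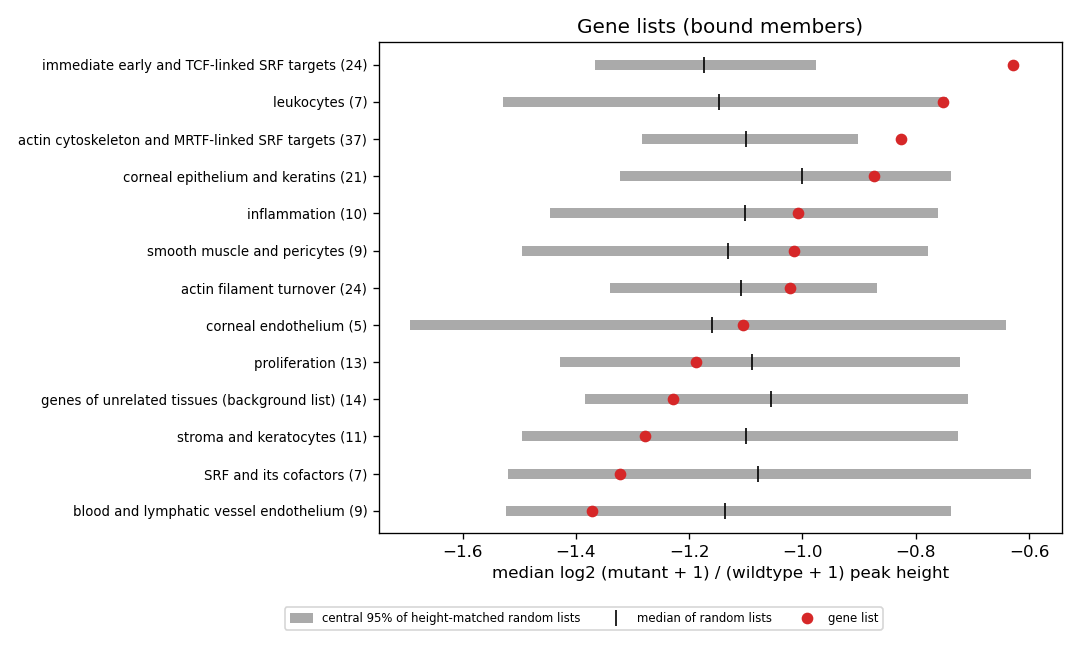
Median log2 ratio of mutant to wildtype peak height for each of the 13 gene lists (points), with the number of bound members in parentheses, beside the central 95% (bars) and median (ticks) of height-matched random lists. The immediate early list (-0.63) and the actin list (-0.83) lie to the right of their bars, and the other 11 lists lie on theirs.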

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

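Tied, shared-region, location-matched, autosomal, both-called, gene-start ratio and 5-member alternatives were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library. Input-based and motif-based alternatives were not run. The immediate early list stayed above the 97.5th percentile with the average value, the mean over regions, location matching, gene-start regions, either tie rule, shared regions counted once and without 5 members; a pseudocount of 5 and scaling were not run for lists. Why values moved between these settings was not tested, except where fewer regions entered. At or above the median interval height of 24, 5708 mutant and 19278 wildtype intervals remained, overlaps were 99.7% of mutant and 69.0% of wildtype intervals, and 17.9% of wildtype intervals were at promoters. At 50% reciprocal overlap the shares were 92.7% and 48.6%, with summits within 100 bp 89.8% and 47.1%, and with equal numbers 75.5% and 74.8%. Among regions at or above a height of 28, 9 were called in mutant only and 4132 in wildtype only, 14 were 2-fold higher in mutant and 11285 in wildtype, and the median was -1.21. The average value gave 11307 regions 2-fold higher in wildtype, a median of -0.83 and 1 list above the central range. A pseudocount of 5 gave 65 regions 2-fold higher in mutant and a median of -0.93. Common scaling, which sets the median near 0 by construction, gave 1459 and 2962 regions and a median of -0.090. Regions called in both gave a median of -0.96. Within 5 kb, 39.4% of mutant and 33.9% of wildtype intervals were at promoters. With intervals within 1 kb of a start, 2 lists were bound above random lists in mutant. With the mean over regions, the actin list median was -0.56 and 1 list, vessels, lay below the central range; with regions within 1 kb of a start the actin median was -0.42 and that of 3 SRF and cofactor genes turned to 0.18. The Srf region at 46552629 turned to 0.31 with the average value and 0.97 with scaling, and that at 46555631 to 0.87 with scaling. Depth is unknown, so its limit on low regions could not be computed.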

Other observations

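Regions with a mean height of at least 50 were ranked by ratio, a set chosen after its values were seen. Of the 50 regions with the highest ratios, 7 carried a gene of the SRF-linked lists (14%, exact binomial 95% interval 5.82 to 26.7), against 36 of all 2312 such regions (1.56%). This count largely restates the immediate early result given with the gene lists, since it ranks the same ratios and 4 of the 7 carry a gene of that list. The other 3 (6%, 1.25 to 16.5) stand against 22 of all such regions (0.952%). The 7 include Egr2 (54 in mutant and 59 in wildtype), Fosb (55 and 61), Fos (97 and 108), Junb (83 and 98) and Vcl, the vinculin gene (50 and 60). Of the 50 regions with the lowest ratios, 0 did, with an upper limit of 7.11% that also holds the share of all such regions. These include Wasf1, an actin nucleation regulator gene outside the lists (13 and 143), Traf6 (13 and 112) and Clip4 (5 and 104). Actn4, an alpha-actinin gene also chosen after its values were seen, went the other way from its list, with 46 in mutant and 22 in wildtype. Promoter regions had a median log2 ratio 0.40 above that of other regions of like height (95% bootstrap interval 0.38 to 0.42), but 0.081 over regions called in both libraries (0.056 to 0.098) and -0.13 over regions of mean height 50 or more (-0.17 to -0.080). Regions on chromosome X had a median log2 ratio of -1.27 over 634 regions, against -1.10 on autosomes. Their median wildtype height was also lower, at 20 against 28, and this contrast was not matched on height.

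All tests below were chosen after the values they bear on had been seen, at least in part. Heights were lower in the mutant library at 95.4% of regions. A lower depth acting as 1 common factor would lower all regions alike. The immediate early list, at percentile 100 of height-matched lists, argues against this for the median of its 24 genes only. It does not do so for each gene, as 8 of them were at least 2-fold lower in mutant. That list cannot decide what lowered the other regions, so depth or scaling as the cause of the general shift stays open. Scaling by a common factor of 2.1 took the median log2 ratio to -0.090, near 0 by construction. Read totals were not used. A weaker immunoprecipitation as the whole cause was weighed on the premise that known targets would lose at least as much as other regions. The 4 SRF-linked lists together were at percentile 99.99 (99.89 with average values, 99.3 without the immediate early list). Of these lists alone, actin filament turnover was at 78.2, SRF with its cofactors at 14.8 and, with average values, the actin list at 92.8. The premise was not tested and each genotype had 1 library, so a weaker immunoprecipitation cannot be told apart from the genotype. More capture of regions without an SRF link in the wildtype library cannot be told apart from the genotype, with the background list at percentile 14.3 and 1 library per genotype. The genotype stays an open explanation that was not tested.

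By their median, regions of the immediate early list kept more of their wildtype height than other regions. Height as the cause is argued against by percentile 100 among height-matched lists. Promoter and CpG island location is argued against by percentile 100 among lists matched on these and on 5 coarser height classes. Under that matching the leukocyte list, without a known SRF link, was also high, at percentile 98.4. A few members carrying the list is argued against by percentile 99.98 without the 5 members of highest ratio. A difference between these libraries other than genotype was not tested. The true scale between the libraries is unknown, and scaling was not run for lists. Whether binding at the genes of this list was lower, equal or higher in mutant is therefore open. A hypothesis that the mutation affects SRF binding there differently from other regions needs replicate libraries.

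With the Dstn start region, 29 regions at or above the median wildtype height were at 2 or less in mutant. Of these, 17 had a neighbour within 50 kb, and 2 of these neighbours were also at 2 or less (11.8%, exact binomial 95% interval 1.46 to 36.4). Without Dstn, whose neighbour was also at 0, it was 1 of 16 (6.25%, 0.158 to 30.2), and 1.80% of all regions were at 2 or less. The neighbouring regions had a median log2 ratio of -1.70, against -1.10 over all regions. Both intervals span the limit of 20% set for deleted or unmappable DNA reaching past the region, so this explanation cannot be told apart from a local loss of signal. The labels give a mixed strain background, and a sequence difference confined to single regions was not tested.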
